A study of Mus musculus with 16 samples.

How the data were processed

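Small RNA was measured in 16 libraries of mouse mesenchymal stem cells, 2 in each of 8 groups: Dicer f/f and Dicer -/- cells with mCherry, and Dicer -/- cells with human Dicer or its D1320A, D1709A, D1320A/D1709A, K70A or Y971A/Y972A mutants. Per the labels, total RNA was taken with Trizol, RNA of 15 to 50 nt was isolated from a gel, and libraries followed the standard Illumina small RNA procedure. The deposited values are counts: the authors listed each distinct read with the number of times it was sequenced, without trimming, alignment or scaling. The tools used for that step are not given in the sources used here. Reads were 41 nt long in replicate 1 and 51 nt in replicate 2.

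The 3′ adapter given in the labels was removed where 12 of its bases matched, or 5 or more at the end of the read, so that inserts were seen whole up to 36 nt in replicate 1 and 46 nt in replicate 2. Inserts of 15 nt or more numbered 10331036 to 20502254 per library, and this number scaled the libraries. Reads of 18 to 26 nt were matched without mismatch to the sense strand of 1174 miRNA hairpins of GENCODE release M21 (GRCm38), which bear 1087 names. Reads that matched hairpins of different names were left out, and reads of hairpins of the same name were summed. A read was given to the 5p or 3p arm by the side of the hairpin midpoint on which its centre lay, because the annotation gives no mature ends. The genome sequence was not used here, so flanks outside the annotated hairpins, which had been planned, were not searched. Arms with 20 or more reads in total were tested (540 of 577 counted), and hairpins with 20 or more on each arm entered the ratio test (183).

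Usual ends of each arm were the positions most used in wild type, with 10 or more reads. A read counted as running past a cleavage site if its other end lay within 2 nt of the usual end and it ran 5 nt or more past the site. End precision was taken over arms with 20 or more reads in every library compared and is given as the median over arms. Reads of 20 nt or more that matched Dicer1 transcripts in sense, and no transcript of another gene, were counted.

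Group tests used edgeR 4.0.16 quasi-likelihood fits in R 4.3.3 over all 16 libraries at once, 2-sided, with Benjamini-Hochberg adjusted p under 0.05, in 13 comparisons of levels and 7 of 5p to 3p ratios (the arm by group interaction). The common biological coefficient of variation was 2.10. The standard error of a log2 change is the change divided by the square root of F and is approximate. Single values per library were compared by exact permutation, which with 2 against 2 libraries cannot give p under 1 in 3. Where a group held no reads, a fold is given as at least the value against a floor of 3 reads. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for counting and plots, and RNAfold 2.7.2 for folding.

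The tests, the alternatives, the lists and the rule for naming miRNAs were fixed before the data were examined. For each comparison the rule names the 10 passing arms with the highest mean CPM, and the 6 that rose most and the 6 that fell most among passing arms with 10 CPM or more on average and the same direction for both replicate numbers. It also names 2 to 4 members of each list, and miR-451a, miR-320 and miR-484 always; names that recur across comparisons are given in part. The 13 lists were the let-7 family, the miR-17-92 cluster with its paralogs, miRNAs abundant in fibroblasts and mesenchymal cells, p53 targets, the miR-379-410 cluster, mirtrons and capped precursors, miRNAs made without Dicer (miR-451a), and markers of pluripotent cells, blood cells, neurons, muscle, liver and endothelium. Names under which the annotation holds members of these lists (such as miR-18 for miR-18a and miR-92 for miR-92a) were added once the annotation was seen.

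Alternatives covered scaling by TMM or by snoRNA and snRNA reads, DESeq2 1.42.0, no filter on low counts, the replicate block, each library left out in turn, shared reads split equally, reads of 15 to 30 nt with up to 2 unmatched 3′ bases, and for ratios limma 3.58.1 with pseudocounts of 0.5 and 5. TMM took the sum of the miRNA arm reads, not all reads, as library size. Chosen after seeing the data were filters at 10, 50 and 100 CPM (alone, with the block and with limma), arms from the folded loop, library sizes without adapter products, reads that match no other small RNA class, and the 100 CPM bound of the plot of fold changes. Tests were checked on simulated data with changed arms of known fold, drawn whatever their level from arms with reads in the second group. With low spread edgeR recovered 84.2% to 92.9% of 650 changed arms at 4-fold to 256-fold, and 86.7% to 95.2% of 105 changed ratios. With the spread of the data it recovered 0 at 64-fold and 4 at 256-fold of the arms, and 0 of the ratios at any fold. Sequence variants and isomiR tailing were not analysed here.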

Results

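Small RNA was sequenced from 16 libraries of mouse mesenchymal stem cells, 2 libraries in each of 8 groups. Cells with intact Dicer (Dicer f/f, here wild type) and cells without it (Dicer -/-, here knockout) carried mCherry, a red fluorescent protein that serves as the control transfection. The other groups were knockout cells given human Dicer (hsDicer) or human Dicer with point changes. Dicer cuts the precursor hairpin of a miRNA near its loop and so frees the 5p and the 3p arm. D1320A changes the RNase IIIA domain, which cuts the 3p strand, D1709A the RNase IIIB domain, which cuts the 5p strand, and the double mutant changes both. K70A lies in the helicase domain and Y971A/Y972A in the PAZ domain, which holds the end of the precursor. The question was what each domain contributes to the processing of precursors in cells. The libraries held 10877381 to 21768558 reads, of which 10331036 (knockout, replicate 1) to 20502254 (wild type, replicate 2) had an insert of 15 nt or more. All levels are read counts divided by this number and brought to the CPM scale, and every mean ± SD is over 2 libraries. Replicate 1 libraries had reads of 41 nt and replicate 2 libraries reads of 51 nt, so values are also given per replicate. The labels do not say that the replicates came from separate cultures, so the p-values measure the spread between these samples. In the fits of levels edgeR took this spread wholly from a trend shared by arms of similar abundance. The SE and p of an arm therefore do not reflect how well its own libraries agree. Reads were not counted as separate molecules, and limits from counts cover counting error only.

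Reads that matched mouse Dicer1 transcripts, the targeted gene, were found at 0 and 0.0488 CPM in wild type and at 0.0968 and 0.0626 CPM in the knockout (replicates 1 and 2). They stood at 0 and 1.44 CPM with hsDicer, 22.1 and 16.4 with D1320A, 0.859 and 0.290 with D1709A, 0.121 and 4.10 with the double mutant, 139.8 and 12.7 with K70A and 0.170 and 13.1 with Y971A/Y972A. These reads check nothing about the labels, because the labels do not give the deleted part of the gene and short reads shared by human and mouse Dicer cannot be told apart.

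miRNA reads made up 42.4% ± 6.99 of wild-type reads and 0.919% ± 0.884 of knockout reads. hsDicer brought them to 26.2% ± 16.7, K70A to 25.7% ± 7.48 and Y971A/Y972A to 16.2% ± 13.5. With D1320A the miRNA share was 3.38% ± 1.73, with D1709A 5.59% ± 2.62 and with the double mutant 0.573% ± 0.306. Replicates 1 and 2 gave 47.4% and 37.5% in wild type, 1.54% and 0.293% in the knockout, 38.1% and 14.4% with hsDicer, 4.61% and 2.16% with D1320A and 7.44% and 3.74% with D1709A. The double mutant gave 0.789% and 0.356%, K70A 31.0% and 20.4% and Y971A/Y972A 25.8% and 6.67%. Both knockout libraries lay below both hsDicer libraries and below both D1320A and both D1709A libraries, separations for each of which the 2-sided exact permutation test gives p = 0.333, the smallest that 2 against 2 libraries allow. hsDicer and K70A overlapped (exact permutation p = 1), as did hsDicer and Y971A/Y972A (p = 0.667 by the same exact test), which takes no account of replicate numbers. The share was higher in replicate 1 in all 8 groups, and within each replicate number Y971A/Y972A lay below hsDicer.

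**Figure D1:**
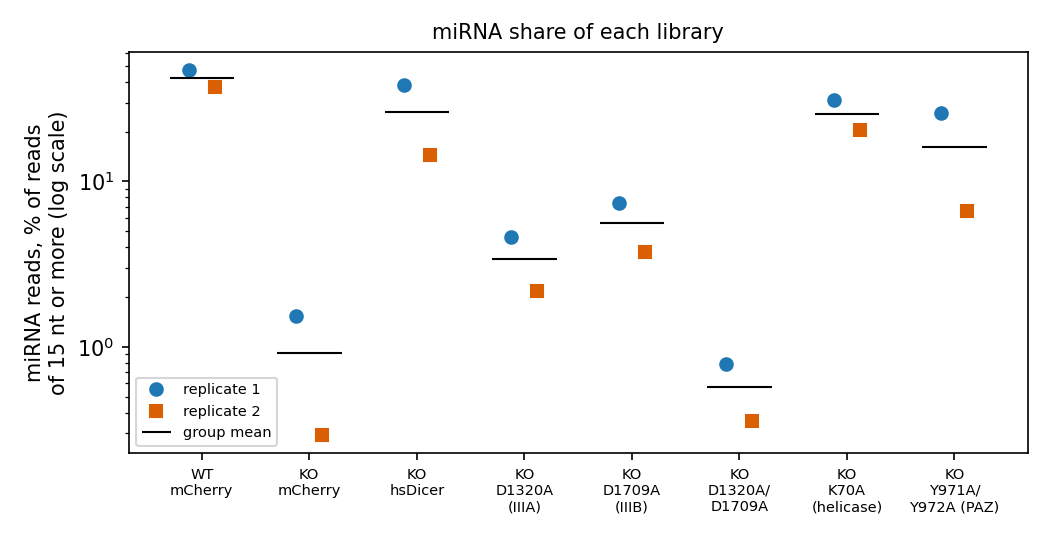
Share of reads of 15 nt or more that matched a miRNA (percent, log axis) in each library of the 8 groups, with a point for each library and a line at the group mean. Wild-type libraries lie at 47.4% and 37.5%, knockout libraries at 1.54% and 0.293% and double-mutant libraries at 0.789% and 0.356%.

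Comparison of the knockout with wild type asked which miRNAs need Dicer. With scaling to all reads, 19 5p arms and 12 3p arms fell in the knockout and none of the 540 arms tested rose. TMM and DESeq2, which assume that most arms stay level, also called arms that rose. miRNA reads, however, made up 47.4% and 37.5% of wild-type reads and 1.54% and 0.293% of knockout reads. With scaling to all reads 209 of 278 5p arms and 202 of 262 3p arms were lower in the knockout. These values argue against that assumption in this comparison. DESeq2 turned the direction of some arms named here, and TMM turned none of them. miR-22-3p, the most abundant arm, fell from 145748 ± 48849 to 1668 ± 1699.8 CPM, a log2 change of -6.45 (SE 0.74), adjusted p = 2.13e-15 by edgeR. miR-21a-5p, a miRNA often raised in tumours, stood at 51072 ± 14577 CPM in wild type and changed by -4.64 (SE 0.90). miR-29b-3p, which targets collagen transcripts, changed by -7.71 (SE 1.08) from 36062 ± 24274 CPM. miR-24-3p changed by -7.83 (SE 1.54), miR-99b-5p by -7.83 (SE 1.55), miR-125b-5p by -7.71 (SE 1.58), miR-26a-5p by -7.95 (SE 1.71) and miR-31-5p by -6.86 (SE 1.60). The strongest falls among passing arms of 10 CPM or more were those of miR-193a-3p (-8.56), miR-222-3p (-8.50), miR-24-5p (-8.38), miR-214-3p (-8.11), miR-151-5p (-8.10) and miR-143-3p (-8.05). All of these were lower in the knockout for both replicate numbers. Without knockout replicate 1 the count was 11, without knockout replicate 2 it was 8 and without wild-type replicate 1 it was 20. TMM scaling left 1 arm that fell and 4 that rose, and DESeq2 gave 6 that fell and 14 that rose, with miR-22-3p at 0.86, miR-21a-5p at 2.68 and miR-31-5p at 0.50. Scaling by snoRNA and snRNA reads called 12 arms.

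Knockout replicate 1 held all 151 fragments that matched no miRNA, had 2000 or more reads in wild-type replicate 1 and none in any replicate 2 library, at 0.236% of their wild-type reads. Of 102 arms with 2000 or more reads in wild-type replicate 1, 90 stood in knockout replicate 1 at no more than 2 times this percentage, with a median over all 102 of 0.285% (quartiles 0.225% and 0.350%). The falls of such arms therefore rest on a replicate 1 level close to that of these fragments. Some of the hairpins named here lie, in GRCm38, as follows: Mir22 on chromosome 11 at 75463716 to 75463810 (plus strand) within an exon of Mir22hg, Mir21a on chromosome 11 at 86584067 to 86584158 (minus strand) within an exon of Vmp1, and Mir31 on chromosome 4 at 88910557 to 88910662 (minus strand). miR-29b has a pair of hairpins, Mir29b-1 on chromosome 6 at 31063023 to 31063093 (minus strand) and Mir29b-2 on chromosome 1 at 195037040 to 195037120 (plus strand). Mir27b on chromosome 13 at 63300712 to 63300784 (plus strand) belongs to the miR-23b cluster, Mir378a on chromosome 18 at 61397835 to 61397900 (minus strand) lies in an intron of Ppargc1b, and Mir99b on chromosome 17 at 17830188 to 17830257 (plus strand) in an intron of Spaca6.

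Of 18 arms of the let-7 family, which holds back proliferation, 6 fell in the knockout over all arms and 9 adjusted over the list alone. The 6 were let-7c-5p (-7.36), let-7b-5p (-7.92), let-7f-5p (-7.84), let-7a-5p (-7.61), let-7d-3p (-7.34) and let-7d-5p (-7.52), with the family's median at -7.62 and at -0.15 under DESeq2, where let-7c-5p turned to 0.14. Among 18 arms of the miR-17-92 cluster and its paralogs, which promote growth, 1 fell (miR-92-3p, -7.64) and 1 adjusted over the list alone, and the median of -7.07 turned to 0.51 under DESeq2. Among 68 arms abundant in fibroblasts and mesenchymal cells 15 fell, while adjusted over the list alone 24 fell and 1 rose, with a median of -7.66 (-0.15 under DESeq2). No arm of the other lists passed edgeR's test over all arms: p53 targets (6 arms, 0 with an unadjusted p under 0.05), the miR-379-410 cluster (2, 0), mirtrons and capped precursors (7, 2), miR-451a (1, 0), and the marker miRNAs of pluripotent cells (2, 0), blood cells (6, 1), neurons (4, 0), muscle (2, 1), liver (1, 0) and endothelium (2, 1). Adjusted over the list alone, 1 arm of the endothelial list fell and 0 arms of the remaining lists changed, and DESeq2 called 1 arm, miR-451a-5p, higher in the knockout.

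hsDicer against the knockout asked what human Dicer restores in mouse cells without Dicer. With scaling to all reads 20 5p arms and 12 3p arms rose and none fell. miR-22-3p stood at 74635 ± 48314 CPM with hsDicer and rose by 5.48 (SE 0.71) on the log2 scale, adjusted p = 5.83e-12 by edgeR. miR-29b-3p rose by 7.54 (SE 1.07) to 32016 ± 11792 CPM, and miR-21a-5p by 4.10 (SE 0.88) to 35129 ± 29532 CPM, though DESeq2's scaling turned miR-21a-5p to -2.73 and miR-22-3p to -1.21. The largest rises among passing arms of 10 CPM or more were those of miR-7-5p (8.88), miR-378a-3p (8.72), miR-193a-3p (8.43), miR-92-3p (8.18), miR-182-5p (8.08) and miR-222-3p (7.94), each higher for both replicate numbers. Of 18 let-7 arms 6 rose (10 adjusted over the list alone), with let-7c-5p at 6.76 and -0.21 under DESeq2. Of 18 arms of the miR-17-92 group 1 rose (4 adjusted over the list alone) and of 68 fibroblast and mesenchymal arms 14 rose (19 adjusted over the list alone), with medians of 5.66 and 6.24 that DESeq2 turned to -0.52 and -0.29. The count was 8 without hsDicer replicate 1, 7 without knockout replicate 1 and 5 without knockout replicate 2. TMM gave 1 arm that rose and 3 that fell, DESeq2 5 and 14, and scaling by snoRNA and snRNA reads called only 3 arms. The snoRNA reads themselves differed between replicates 1 and 2, at 42602 and 196877 CPM with hsDicer and 79724 and 241590 CPM in the knockout. They were higher in replicate 2 in every group. What this adds to the spread under that scale was not tested.

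hsDicer cells were also compared with wild type, which keeps its own Dicer. No arm passed edgeR's test, with 2 5p and 4 3p arms at an unadjusted p under 0.05, while DESeq2 called 16 arms (7 higher and 9 lower with hsDicer) and limma on arms of 10 CPM or more, a test chosen after seeing the data, called 0. miR-22-3p stood at 74635 ± 48314 CPM with hsDicer and 145748 ± 48849 CPM in wild type, a log2 difference of -0.97 (SE 0.59). For let-7c-5p the difference was -0.60 (SE 1.04), for miR-29b-3p -0.17 (SE 0.80) and for miR-21a-5p -0.54 (SE 0.78), each within 2 standard errors of 0. In simulated data with the spread of these libraries, edgeR recovered 0 of 650 arms changed 16-fold, so a count of 0 does not show that arms were alike. The simulated arms were drawn whatever their level, so this value is not the power for abundant arms alone. No arm of the let-7, miR-17-92 or fibroblast lists passed edgeR's test over all arms or adjusted over the list alone, with 0, 0 and 1 at an unadjusted p under 0.05.

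D1320A against hsDicer asked which arms need the RNase IIIA site. Of the arms that passed the test, 10 were 3p arms and 1 a 5p arm, all lower with D1320A. miR-22-3p stood at 185 ± 70.9 CPM against 74635 ± 48314 CPM, a log2 change of -8.65 (SE 0.81), adjusted p = 2.49e-23 by edgeR. miR-29b-3p changed by -8.87 (SE 1.13), miR-24-3p by -8.26 (SE 1.56), miR-29a-3p by -5.76 (SE 1.67), miR-143-3p by -7.97 (SE 2.14) and miR-140-3p by -6.93 (SE 2.06). The deepest falls among passing arms of 10 CPM or more were those of miR-27b-3p (-11.45), miR-378a-3p (-10.90), miR-423-3p (-9.54) and miR-214-3p (-8.98). miR-21a-5p was the 5p arm that passed, at -3.13 (SE 0.84). All were lower for both replicate numbers, and with TMM and snoRNA scaling all arms called were lower too, though scaling by snoRNA and snRNA reads called only 2. Of 68 fibroblast and mesenchymal arms 7 3p and 1 5p arm fell (11 adjusted over the list alone), with a list median of -2.31 that DESeq2 turned to 0.44. No let-7 arm passed edgeR's test over all arms or adjusted over the list alone (3 at an unadjusted p under 0.05, 0 with DESeq2 or TMM), and let-7c-5p stood at 2277 ± 1974 CPM against 11506 ± 10139 CPM. The count was 3 without D1320A replicate 1, the same without D1320A replicate 2, and 3 without hsDicer replicate 1. TMM called 4 arms, all lower 3p arms, and DESeq2 50, of which 13 rose and 37 fell.

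D1709A against hsDicer asked the same of the RNase IIIB site. All 18 arms that passed were 5p arms and lower with D1709A, and 0 of 262 3p arms passed edgeR's test (4 at an unadjusted p under 0.05), whereas DESeq2 called 28 3p arms higher and limma on arms of 10 CPM or more 2. miR-21a-5p stood at 864 ± 228 CPM against 35129 ± 29532 CPM, a log2 change of -5.35 (SE 0.93), which DESeq2's scaling turned to 0.65. let-7c-5p changed by -6.92 (SE 1.34), let-7i-5p by -7.89 (SE 1.61), let-7b-5p by -7.26 (SE 1.63) and miR-26a-5p by -7.63 (SE 1.69). miR-99b-5p (-5.81), miR-125b-5p (-5.90), miR-31-5p (-5.52), miR-125a-5p (-6.18) and miR-96-5p (-6.42) fell too, although miR-125b-5p stood at 0.051 and miR-31-5p at 0.11 under DESeq2. The deepest falls among passing arms of 10 CPM or more were those of let-7a-5p (-9.83), miR-30e-5p (-8.78), miR-28a-5p (-8.59), let-7i-5p (-7.89), miR-30d-5p (-7.73) and miR-26a-5p (-7.63). All were lower for both replicate numbers. miR-22-3p, which passed in the D1320A comparison, stood at 29472 ± 7613 CPM with D1709A, a log2 difference of -1.34 (SE 0.59) that did not pass. Of 18 let-7 arms 5 fell, all 5p (9 adjusted over the list alone), with a median of -6.38 (-0.90 under DESeq2). Of 68 fibroblast and mesenchymal arms 9 fell, all 5p (9 adjusted over the list alone), with a median of -3.55 that DESeq2 turned to 1.26. The count was 2 without D1709A replicate 1, 1 without D1709A replicate 2 and 10 without hsDicer replicate 1. TMM called 3 arms, all lower 5p arms, and DESeq2 called 29 that rose and 2 that fell. Scaling by snoRNA and snRNA reads called 4 arms.

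**Figure D2:**
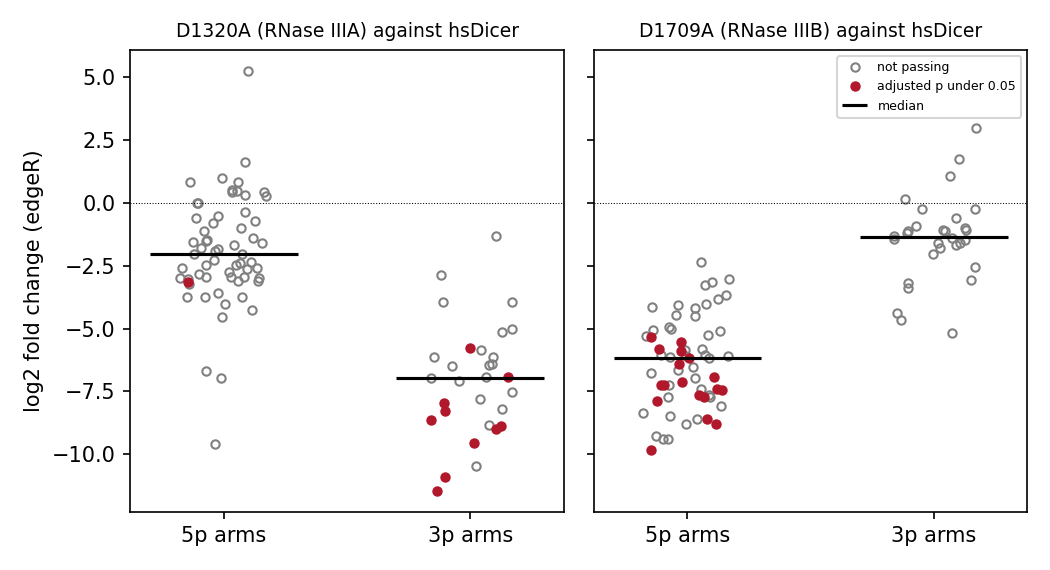
edgeR log2 fold changes against hsDicer of the arms with a mean of 100 CPM or more, a bound chosen after seeing the data, with 5p and 3p arms side by side for D1320A and D1709A, filled points for arms that passed the test and lines at the medians. For D1320A the medians were -2.03 (5p, 61 arms) and -6.95 (3p, 30 arms), for D1709A -6.19 and -1.36. Over all 278 5p and 262 3p arms tested they were 0 and -5.14 for D1320A, with 120 5p arms lower and 125 higher, and -4.83 and 0 for D1709A, with 125 3p arms lower and 91 higher. DESeq2's scaling turned the sign of arms such as miR-21a-5p with D1709A.

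The balance of the arms within each library does not depend on scaling between libraries. Of all miRNA reads, 96.9% ± 0.545 came from 5p arms with D1320A and 4.12% ± 0.709 with D1709A, against 45.6% ± 5.44 with hsDicer, 45.6% ± 6.26 in wild type, 48.0% ± 12.3 with K70A, 38.6% ± 1.70 with Y971A/Y972A, 72.6% ± 0.0969 with the double mutant and 67.4% ± 2.36 in the knockout. Replicates gave 97.3% and 96.6% with D1320A, 3.62% and 4.62% with D1709A and 49.4% and 41.7% with hsDicer, so both mutants lay outside the range of every other group's libraries. With D1320A, 5p arms held 32856 CPM and 3p arms 988 CPM, and with D1709A 2209.7 and 53724 CPM. miR-22, read mainly from 3p in every hsDicer library, gave 15786 5p and 5202 3p reads with D1320A, 9643 5p and 2328410 3p reads with hsDicer and 116 5p and 695665 3p reads with D1709A. miR-24 gave 49702 5p and 710 3p reads with D1320A and 266 5p and 86722 3p reads with D1709A. let-7i gave 721 5p and 1012 3p reads with D1709A and 217753 5p and 480 3p reads with hsDicer. These hairpins, and those named in the test of ratios, were chosen after their values were seen.

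**Figure D3:**
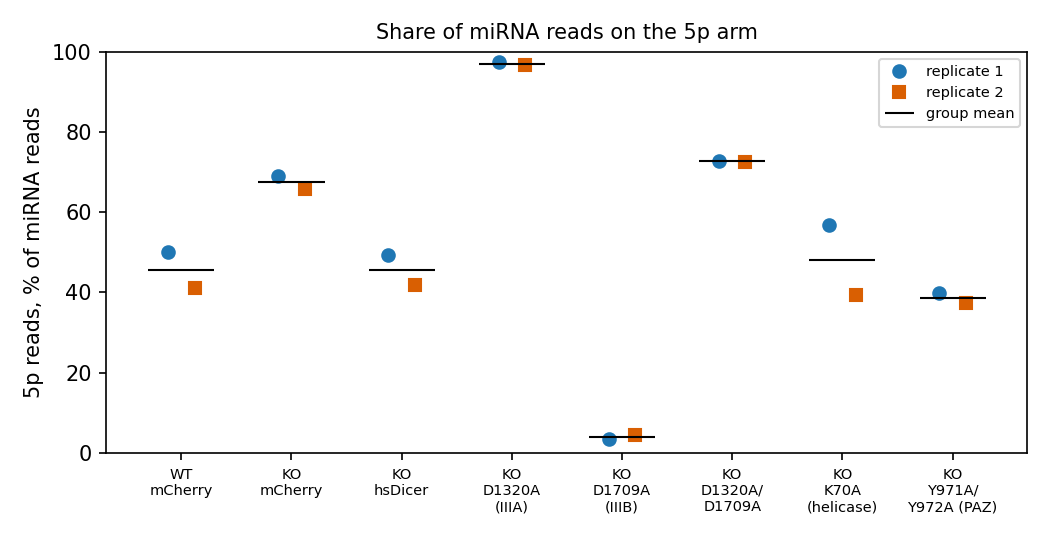
Percent of miRNA reads that come from the 5p arm in each library of the 8 groups, with a line at each group mean. D1320A libraries lie at 97.3% and 96.6%, D1709A libraries at 3.62% and 4.62% and hsDicer libraries at 49.4% and 41.7%.

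The median log2 ratio of 5p to 3p reads over 183 hairpins was 5.84 and 4.61 with D1320A (replicates 1 and 2), -1.67 and -0.44 with D1709A, and 0 and 1.61 with hsDicer, where hairpins without reads in a library count as 0. Over hairpins with 20 or more reads in the library, a bound chosen after seeing the data, it was 6.75 and 7.21 with D1320A and -4.56 and -4.27 with D1709A. On this measure hsDicer gave 9.08 and 1.93 and wild type 10.51 and 1.45, so D1320A lay below hsDicer in replicate 1 and above it in replicate 2, while D1709A lay below both in each. With D1320A, 101 of 122 and 87 of 103 hairpins with 100 or more reads had over 90% of them on 5p, and with D1709A 73 of 110 and 56 of 85 had under 10% there (bounds chosen after seeing the data). Over 90% on 5p was also seen in 20 of 24 and 34 of 58 with the double mutant, 21 of 34 and 27 of 45 in the knockout and 48 of 81 and 60 of 151 with hsDicer. Among hairpins with 20 or more reads in each library compared, the 5p share was higher than with hsDicer for both replicate numbers in 26 of 71 and lower in 8 with D1320A, and higher in 0 of 58 and lower in 34 with D1709A. Tested one by one over 183 hairpins with edgeR and no term for replicate number, no ratio passed in any of the 7 comparisons, with 34 at an unadjusted p under 0.05 for D1320A against D1709A, 11 for D1320A and 3 for D1709A against hsDicer, 1 for Y971A/Y972A against hsDicer and 0 in each of the others. limma on the log2 ratio called 48 hairpins for D1320A against D1709A, all toward 5p, and 10 for D1320A against hsDicer, 8 toward 5p and 2 toward 3p. With a larger pseudocount limma called 51 and 11, 14 toward 3p for D1709A and 3 for the double mutant. In edgeR the D1320A to D1709A difference was 14.80 for miR-22 (SE 5.31), 14.16 for miR-24 (SE 5.09) and 15.94 for miR-193a (SE 5.79), each with adjusted p = 0.203 and in the same direction for both replicate numbers. For miR-29b the D1320A to hsDicer difference was 14.10 (SE 5.93), and for miR-26a the D1709A to hsDicer difference was -12.31 (SE 5.69).

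Reads that run past a usual cleavage site come from RNA not cut at that site, which need not be a whole precursor. On hairpins with at most 44 nt between the arm starts, some reads past the usual 5p end had a seen end away from the 3p start. Their share ranged from 0.388% (hsDicer replicate 1) to 57.2% (knockout replicate 1). With D1320A, 93.7% and 97.4% of reads that ended at the 3p end began 5 nt or more before the usual 3p start (151727 of 161933 and 167069 of 171493 reads in replicates 1 and 2). In wild type, hsDicer, D1709A, K70A and Y971A/Y972A this share was 0.127% or less in every library, in the knockout 0.124% and 7.99% and with the double mutant 0.0114% and 11.96%. With D1709A, 80.2% and 81.3% of reads from the 5p start ran 5 nt or more past the usual 5p end, against 0.477% and 8.54% with hsDicer and 0.000892% and 0.479% in wild type. The knockout gave 43.4% and 84.3%, the double mutant 36.2% and 62.0%, D1320A 14.0% and 15.5%, K70A 0.837% and 1.71% and Y971A/Y972A 2.09% and 5.54%. In D1320A libraries 201100 and 168274 reads began at the 5p cleavage site and ran into 3p, a count chosen after seeing the data. Exact permutation tests of D1320A (3p) and D1709A (5p) against hsDicer each gave p = 0.333, the smallest possible. Inserts longer than the reads were not seen to their end. The 3p share counts only reads whose end was seen, so inserts of up to 36 nt in replicate 1 and 46 nt in replicate 2. Longer uncut precursors that were sequenced are left out of the 3p share but counted in the 5p share. Low 3p shares in the knockout and the double mutant therefore do not show cleavage at the 3p site. The RNA was also selected by size from a gel before sequencing. Uncut precursors above that size range can be missed by both shares, and how many were lost was not measured. The 5p shares of the knockout and D1709A therefore do not compare amounts of whole precursor.

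**Figure D4:**
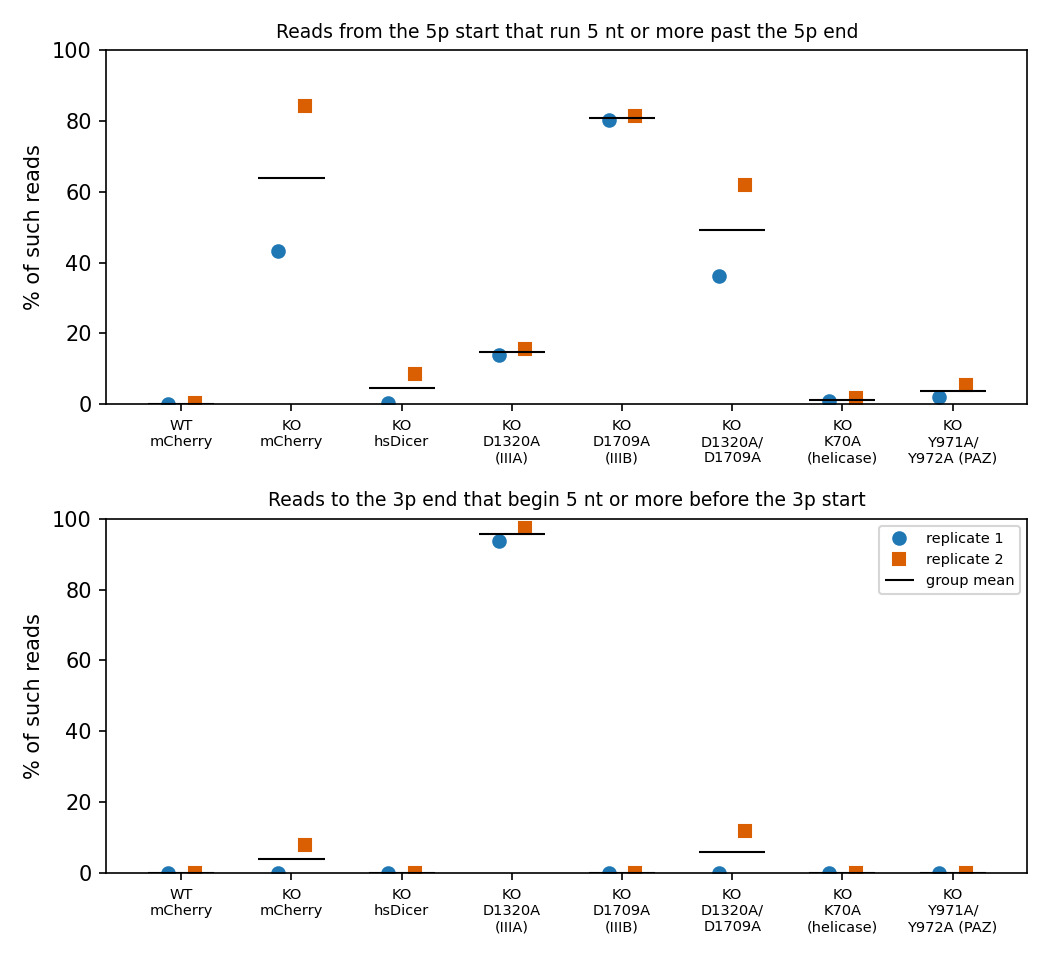
Percent of reads from the 5p start that ran 5 nt or more past the usual 5p end, and percent of reads to the 3p end that began 5 nt or more before the usual 3p start, for each library of the 8 groups. D1709A lies at 80.2% and 81.3% on the 5p side and D1320A at 93.7% and 97.4% on the 3p side. The 3p side counts only reads whose end was seen, which leaves out longer uncut precursors. Precursors above the size range taken from the gel can be missed on both sides.

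The double mutant against hsDicer asked what is left with both catalytic sites changed. 26 5p arms and 17 3p arms fell and none rose with scaling to all reads. miR-22-3p stood at 751 ± 564 CPM, a log2 change of -6.63 (SE 0.75), adjusted p = 4.62e-16 by edgeR. miR-29b-3p changed by -7.19 (SE 1.05), let-7c-5p by -8.04 (SE 1.41), miR-24-3p by -7.66 (SE 1.53) and miR-21a-5p by -4.15 (SE 0.88), while DESeq2's scaling turned miR-22-3p to 2.41, miR-29b-3p to 1.48 and miR-21a-5p to 4.87. The deepest falls among passing arms of 10 CPM or more were those of miR-191-5p (-10.63), miR-27b-3p (-10.60), miR-155-5p (-10.42), miR-93-5p (-10.41), miR-10b-5p (-10.35) and miR-22-5p (-10.28). Of 18 let-7 arms 7 fell (9 adjusted over the list alone), of 18 arms of the miR-17-92 group 2 (6 adjusted over the list alone), of 68 fibroblast and mesenchymal arms 20 (27 adjusted over the list alone) and of 6 blood-cell arms 1 (1 adjusted over the list alone), which was miR-155-5p. These list medians were -7.83, -7.31, -6.75 and 0, and -0.10, -0.28, 0.21 and 0 under DESeq2. The count was 10 without double-mutant replicate 1, 14 without double-mutant replicate 2 and 21 without hsDicer replicate 1. TMM called 1 arm that rose and 0 that fell, DESeq2 35 and 2. Both assume that most arms stay level. miRNA reads, however, made up 0.789% and 0.356% of reads with the double mutant and 38.1% and 14.4% with hsDicer. With scaling to all reads 191 of 278 5p arms and 184 of 262 3p arms were lower. These values argue against that assumption in this comparison.

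Against the knockout, the same mutants show what a single remaining site yields. With D1320A the arms that rose were all 5p: miR-24-5p by 7.59 (SE 2.12), miR-99b-5p by 6.66 (SE 1.47), miR-31-5p by 6.04 (SE 1.54) and let-7c-5p by 4.43 (SE 1.19), from 106 ± 2.98 to 2277 ± 1974 CPM, while TMM scaling called no arm higher. miR-22-3p changed by -3.17 (SE 0.63) with D1320A, from 1668 ± 1699.8 to 185 ± 70.9 CPM. With D1709A the arms that rose were all 3p: miR-22-3p by 4.14 (SE 0.66) to 29472 ± 7613 CPM, miR-29b-3p by 6.05 (SE 1.001) to 11425 ± 9487 CPM and miR-24-3p by 6.14 (SE 1.42) to 3551 ± 2605 CPM. Of the let-7 arms 1 rose with D1320A (2 adjusted over the list alone) and 0 with D1709A (adjusted over the list alone, 1 rose and 1 fell; 2 at an unadjusted p under 0.05 by edgeR). Of the fibroblast and mesenchymal arms 3 rose and 1 fell with D1320A (3 and 1 adjusted over the list alone), and 3 rose with D1709A (4 adjusted over the list alone). For the double mutant no arm passed edgeR's test over all arms without a term for replicate number (7 5p and 2 3p arms at an unadjusted p under 0.05), while adjusted over the list alone 1 let-7 arm and 2 fibroblast and mesenchymal arms fell. With filters chosen after seeing the data edgeR called 2 arms lower on arms of 10 CPM or more, 2 at 50 and 1 at 100, and without knockout replicate 2 it called 1, while limma on arms of 10 CPM or more called 0, TMM 4 and DESeq2 49. miR-22-3p stood at 751 ± 564 CPM against 1668 ± 1699.8 CPM. For D1320A the count of 5 became 2 and 3 without D1320A replicate 1 or 2 and 0 and 1 without knockout replicate 1 or 2. Scaling by snoRNA and snRNA reads left 0 arms in both comparisons, TMM called 8 arms lower with D1320A and 3 higher and 4 lower with D1709A, and DESeq2 called 13 higher and 37 lower with D1320A and 50 higher and 18 lower with D1709A.

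K70A asked whether the helicase domain matters. Against hsDicer no arm passed edgeR's test (1 5p and 1 3p arm at an unadjusted p under 0.05), limma on arms of 10 CPM or more called 0 and DESeq2 14, 4 higher and 10 lower. miR-22-3p stood at 71894 ± 10153 CPM, a log2 difference from hsDicer of -0.054 (SE 0.58), and let-7c-5p at 13813 ± 16275 CPM, a difference of 0.26 (SE 1.03). No let-7, miR-17-92 or fibroblast arm passed that test over all arms or adjusted over the list alone (0, 0 and 0 at an unadjusted p under 0.05). Against the knockout 20 5p and 10 3p arms rose and none fell. miR-22-3p rose by 5.43 (SE 0.71), miR-29b-3p by 7.24 (SE 1.06), miR-24-3p by 7.21 (SE 1.495) and miR-21a-5p by 3.98 (SE 0.88), but under DESeq2 miR-22-3p stood at -1.36 and miR-21a-5p at -2.95. The largest rises among passing arms of 10 CPM or more were those of miR-99b-5p (8.70), miR-182-5p (8.55), miR-378a-3p (8.29), miR-7-5p (8.20), miR-92-3p (8.03) and miR-222-3p (7.999). Of 18 let-7 arms 4 rose (10 adjusted over the list alone), let-7c-5p by 7.03 (-0.14 under DESeq2), of 18 arms of the miR-17-92 group 1 (4 adjusted over the list alone) and of 68 fibroblast and mesenchymal arms 14 (17 adjusted over the list alone), with list medians of 6.76, 7.33 and 6.37 (-0.30, 0.43 and -0.12 under DESeq2). The count was 11 without K70A replicate 1, 7 without knockout replicate 1 and 6 without knockout replicate 2. TMM called 0 arms that rose and 2 that fell, DESeq2 6 and 14, and scaling by snoRNA and snRNA reads called only 4 arms.

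Y971A/Y972A asked the same of the PAZ domain. Against hsDicer no arm passed edgeR's test (8 5p and 4 3p arms at an unadjusted p under 0.05), limma on arms of 10 CPM or more called 2 and DESeq2 24, 7 higher and 17 lower. miR-22-3p stood at 60091 ± 54134 CPM, a log2 difference from hsDicer of -0.31 (SE 0.58), and let-7c-5p at 2174 ± 2391 CPM, a difference of -2.40 (SE 1.09). No let-7, miR-17-92 or fibroblast arm passed that test over all arms or adjusted over the list alone (3, 0 and 2 at an unadjusted p under 0.05). Against the knockout 14 5p and 7 3p arms rose and none fell. miR-22-3p rose by 5.17 (SE 0.70), miR-29b-3p by 6.46 (SE 1.02), miR-99b-5p by 6.83 (SE 1.48), miR-125b-5p by 6.70 (SE 1.51) and miR-24-3p by 5.43 (SE 1.38), with miR-22-3p at -0.64 under DESeq2. The largest rises among passing arms of 10 CPM or more were those of miR-140-3p (8.91), miR-193a-3p (8.59), miR-7-5p (8.29), miR-28a-5p (8.24), miR-29a-3p (8.11) and miR-92-3p (8.11). Of 18 let-7 arms 2 rose (3 adjusted over the list alone), let-7c-5p by 4.36 (-1.79 under DESeq2), of 18 arms of the miR-17-92 group 1 (1 adjusted over the list alone) and of 68 fibroblast and mesenchymal arms 11 (13 adjusted over the list alone), with list medians of 4.19, 4.85 and 5.28 (-1.26, 0.29 and 0 under DESeq2). The count was 5 without Y971A/Y972A replicate 1 and 2 without knockout replicate 1 or without knockout replicate 2. TMM called 1 arm that rose and 3 that fell, DESeq2 8 and 16, and scaling by snoRNA and snRNA reads called only 2 arms.

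The ends that Dicer makes were compared over 34 5p and 23 3p arms with 20 or more reads in every library compared. The 3′ end of 5p arms that wild type uses most was used by a median of 87.5% and 77.04% of reads in wild type, 90.7% and 81.2% with hsDicer, 80.7% and 72.7% with K70A, 94.5% and 74.3% with Y971A/Y972A and 80.2% and 75.05% with D1320A. For the 5′ end of 3p arms the medians were 99.996% and 97.7% in wild type, 99.99% and 95.3% with hsDicer, 99.97% and 95.4% with K70A, 99.98% and 95.5% with Y971A/Y972A and 97.6% and 98.6% with D1709A. Weighted by reads, Y971A/Y972A used the usual 5′ end of 3p arms in 92.6% and 94.3% of reads and hsDicer in 97.0% and 98.4%. Median lengths of 5p arms were 21.99 nt in wild type, 22.1 nt with hsDicer, 22.1 nt with K70A and 22.1 nt with Y971A/Y972A.

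miR-451a, which matures through Argonaute 2 without Dicer (Mir451a on chromosome 11 at 78073170 to 78073241 (plus strand)), had no reads in wild type or with hsDicer, D1709A or Y971A/Y972A. miR-451a-5p stood at 5.43 ± 2.34 CPM with D1320A (107 and 46 reads in replicates 1 and 2), 1.41 ± 1.99 in the knockout (0 and 45), 4.21 ± 5.95 with the double mutant (0 and 160) and 2.48 ± 3.51 with K70A (0 and 69). In the last 3 groups every read came from replicate 2, and none of the differences passed edgeR's test (0 at an unadjusted p under 0.05). TMM and snoRNA scaling called none either, while DESeq2 called it higher than with hsDicer in these 4 groups, higher in the knockout than in wild type, and lower than in the knockout with D1709A and Y971A/Y972A. miR-320-3p, from a precursor with a capped 5′ end, stood at 794 ± 651 CPM in wild type, 5.05 ± 2.44 in the knockout, 583 ± 580.3 with hsDicer, 3.13 ± 0.355 with D1320A and 99.1 ± 11.2 with D1709A. It stood at 2.10 ± 2.02 with the double mutant, 529 ± 316 with K70A and 440 ± 472 with Y971A/Y972A. miR-484-5p, also from a capped precursor, stood at 241 ± 0.929 CPM in wild type, 0.945 ± 0.717 in the knockout, 288 ± 212 with hsDicer, 374 ± 30.1 with K70A and 7.96 ± 11.02 with Y971A/Y972A. With D1320A miR-484-5p stood at 0.363 ± 0.0486 CPM, with D1709A at 17.1 ± 6.25 and with the double mutant at 0.445 ± 0.114. Over all arms neither passed edgeR's test in any comparison. TMM and snoRNA scaling called no arm of the list of mirtrons and capped precursors, and DESeq2 called 3 lower with D1320A, 1 with K70A and 1 with Y971A/Y972A against hsDicer. Against the knockout DESeq2 called 3 lower with D1320A, 1 higher and 1 lower with D1709A, and 1 lower with each of the double mutant, K70A and Y971A/Y972A. Adjusted over the list of mirtrons and capped precursors alone both fell against hsDicer with D1320A, miR-320-3p by 7.54 (SE 2.84) and miR-484-5p by 9.60 (SE 3.83) on the log2 scale, and with the double mutant, by 8.11 (SE 2.91) and 9.31 (SE 3.79).

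Lists with no arm past edgeR's test over all arms had calls adjusted over the list alone in further comparisons. For hsDicer against knockout this was 1 blood-cell arm that rose, 1 endothelial arm that rose. For D1320A against hsDicer this was 1 miR-17-92 arm that fell, 1 endothelial arm that fell. For D1709A against hsDicer this was 1 blood-cell arm that fell. For the double mutant against hsDicer this was 1 endothelial arm that fell. For D1709A against knockout this was 1 muscle arm that rose. For K70A against knockout this was 1 muscle arm that rose, 1 endothelial arm that rose. For Y971A/Y972A against knockout this was 1 blood-cell arm that rose, 1 muscle arm that rose, 1 endothelial arm that rose. Of these lists and comparisons DESeq2 called 1 miR-17-92 and 1 endothelial arm lower for D1320A against hsDicer and 1 muscle arm higher for D1709A against knockout, and TMM and snoRNA scaling called 0 in each.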

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

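Among the tests in this part, those of all replicate 1 libraries as sources at a single rate and of wild-type replicate 1 as the whole source were chosen after seeing the data. The part first gives values of data that the comparisons do not use. Reads that match mouse Dicer1 averaged 19.3 CPM with D1320A, 0.575 with D1709A, 2.11 with the double mutant, 76.2 with K70A and 6.61 with Y971A/Y972A, and both libraries of each of these groups lay above the highest mCherry library (0.0968 CPM, 1 read). The lower library held only 2 reads with the double mutant, 3 with D1709A and 3 with Y971A/Y972A, within counting error of 1. hsDicer libraries held 0 and 27 reads. Human and mouse Dicer share short stretches, and no explanation was tested.

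miRNA reads made up 1.54% of knockout replicate 1 and 0.293% of knockout replicate 2. Fragments are called private to a library if they match no miRNA, have 2000 or more reads there and none under the other replicate number. Libraries of the same number may share them, so finding them does not tell assigned reads from shared RNA. Of 151 fragments private to wild-type replicate 1, 100% were seen in knockout replicate 1 and 9.93% to 74.2% in other replicate 1 libraries. Reads of wild-type replicate 1 assigned to the knockout may be a source, but at their rate of 0.236% they give only 12.1% of the miRNA reads. That argues against it as the whole source: 12 arms lay above 2 times the rate, led by miR-181a-5p (101% of its wild-type reads), let-7i-5p (5.89%) and miR-125a-5p (5.85%), while the other 90 of 102 abundant arms lay at or below 2 times the rate (median over all 102, 0.285%), so for most arms assigned reads stay open as the source. All replicate 1 libraries at a single rate are excluded, since 12 reads starting at the 5p cleavage site were found where 1305 were expected (0.920%). hsDicer replicate 1 stays open, with 94% of its 150 private fragments seen, at 0.403% of their reads. Of 184 private fragments of K70A replicate 1 only 23.4% were seen, but at 1.70% of their reads, and that library stays open too. Cells that kept Dicer also stay open. None of these 3 was tested. For knockout replicate 2 the test cannot decide, because 100% of only 14 fragments were seen there and 57.1% to 100% in other replicate 2 libraries. The overlap was not limited to the knockout. In replicate 1 the double mutant held 29.1% of the fragments private to wild type, at 0.956% of their reads. It held 97.3% of those private to hsDicer, at 0.314%. D1709A held 100% of those private to K70A (0.362%) and D1320A 91.4% of those private to Y971A/Y972A (0.106%). Other pairs went down to 9.93%. Assigned reads in these libraries were not tested.

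Long reads from the 5p start made up 80.2% and 81.3% of such reads with D1709A. Precursors opened at the 3p site alone would end at the 3p start, and 33.6% of these reads did so within 2 nt in replicate 2 and 42.9% in replicate 1, below the 50% fixed before as the bound for this explanation. In the knockout 0.298% of replicate 2 reads ended there, 33.3 percentage points fewer, which argues against uncut precursors as in the knockout as the whole pattern. In replicate 2 of D1709A, 53.5% of long reads had an end that was not reached. The hairpins counted have at most 44 nt from the 5p start to the 3p start. Inserts were seen whole up to 46 nt in replicate 2, so this 53.5% was longer than that distance. For that library this argues against precursors opened at the 3p site alone as the whole pattern. In replicate 1 inserts were seen whole only up to 36 nt, so its 45.0% cannot decide. A mixture of precursors opened on the 3p strand and uncut ones was not tested.

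In replicate 1 libraries of wild type, hsDicer, K70A and Y971A/Y972A, 26 to 36 of 143 arms with 10 CPM or more in all 4 replicate 2 libraries had no reads, whereas 0 of 56 were missing the other way round. Over 6 pairs of libraries 128 missing arms coincided and 77.04 were expected from independent loss, a ratio of 1.66. Few molecules before amplification (bound under 1.5) and a set of miRNAs absent from, or not captured in, these cultures (bound over 3) cannot be told apart at 1.66, which lies between the bounds. In each of these 4 groups replicate 1 also held fewer distinct sequences of 18 to 26 nt than replicate 2 (38872 and 116448 in wild type), which the test does not use. Replicate number coincides with read length, so a library batch stays open, as does a difference between cultures, which was not tested.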

How the results depend on the processing

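All filters by mean CPM, the limma tests of levels, the arms from the folded loop, the library sizes without adapter products, the reads without other small RNA classes and the bound of 20 reads in the library were chosen after seeing the data. Each count of changed arms was computed in 23 other ways (11 fixed before), and each count of changed ratios in 18. Without the filter on low counts, with shared reads split equally, with wider reads, with arms from the folded loop, without adapter products and without reads of other classes, counts stayed within 1.5 times those reported, which were 31 for knockout against wild type, 32 for hsDicer against knockout, 0 for hsDicer against wild type, 11 for D1320A against hsDicer, 18 for D1709A against hsDicer, 43 for the double mutant against hsDicer, 0 for K70A against hsDicer, 0 for Y971A/Y972A against hsDicer, 5 for D1320A against knockout, 3 for D1709A against knockout, 0 for the double mutant against knockout, 30 for K70A against knockout, 21 for Y971A/Y972A against knockout. Unless stated, the cause was not tested.

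With TMM, counts became 5 for knockout against wild type (4 up, 1 down), 4 for hsDicer against knockout (1 up, 3 down), 4 for D1320A against hsDicer (0 up, 4 down), 3 for D1709A against hsDicer (0 up, 3 down), 1 for the double mutant against hsDicer (1 up, 0 down), 8 for D1320A against knockout (0 up, 8 down), 7 for D1709A against knockout (3 up, 4 down), 4 for the double mutant against knockout (1 up, 3 down), 2 for K70A against knockout (0 up, 2 down) and 4 for Y971A/Y972A against knockout (1 up, 3 down). With DESeq2 they became 20 for knockout against wild type (14 up, 6 down), 19 for hsDicer against knockout (5 up, 14 down), 16 for hsDicer against wild type (7 up, 9 down), 50 for D1320A against hsDicer (13 up, 37 down), 31 for D1709A against hsDicer (29 up, 2 down), 37 for the double mutant against hsDicer (35 up, 2 down), 14 for K70A against hsDicer (4 up, 10 down), 24 for Y971A/Y972A against hsDicer (7 up, 17 down), 50 for D1320A against knockout (13 up, 37 down), 68 for D1709A against knockout (50 up, 18 down), 49 for the double mutant against knockout (35 up, 14 down), 20 for K70A against knockout (6 up, 14 down) and 24 for Y971A/Y972A against knockout (8 up, 16 down). TMM and DESeq2 assume that most arms stay level, and so move the median of all arms by construction: TMM moved knockout against wild type from -6.95 to -3.05, hsDicer against knockout from 5.81 to 2.54, hsDicer against wild type from -0.86 to 0, D1320A against hsDicer from -0.67 to -0.45, D1709A against hsDicer from -2.205 to -0.41, the double mutant against hsDicer from -5.98 to -2.58, Y971A/Y972A against hsDicer from -0.15 to 0, D1320A against knockout from 0.98 to 0, K70A against knockout from 4.71 to 0.70, Y971A/Y972A against knockout from 2.24 to 0, and DESeq2 set to 0 the medians that scaling to all reads puts at -6.95 (knockout against wild type), 5.81 (hsDicer against knockout), -0.86 (hsDicer against wild type), -0.67 (D1320A against hsDicer), -2.205 (D1709A against hsDicer), -5.98 (the double mutant against hsDicer), -0.15 (Y971A/Y972A against hsDicer), 0.98 (D1320A against knockout), 4.71 (K70A against knockout), 2.24 (Y971A/Y972A against knockout). With snoRNA and snRNA reads as the scale, counts became 12 for knockout against wild type, 3 for hsDicer against knockout, 2 for D1320A against hsDicer, 4 for D1709A against hsDicer, 0 for D1320A against knockout, 0 for D1709A against knockout, 4 for K70A against knockout and 2 for Y971A/Y972A against knockout, and medians moved for knockout against wild type from -6.95 to -7.37, hsDicer against knockout from 5.81 to 5.53, hsDicer against wild type from -0.86 to -1.49, D1320A against hsDicer from -0.67 to -0.22, D1709A against hsDicer from -2.205 to -1.80, the double mutant against hsDicer from -5.98 to -5.63, Y971A/Y972A against hsDicer from -0.15 to 0, D1320A against knockout from 0.98 to 1.48, K70A against knockout from 4.71 to 5.38, Y971A/Y972A against knockout from 2.24 to 2.78. With this scale 31 arms were called for the double mutant against hsDicer. TMM took the sum of miRNA arm reads as library size, so its shifts also hold that change of denominator. Against the knockout, 198 of 278 5p and 186 of 262 3p arms were higher with hsDicer under scaling to all reads. With K70A these were 182 and 160. The miRNA share was 38.1% and 14.4% with hsDicer, 31.0% and 20.4% with K70A and 1.54% and 0.293% in the knockout. These values argue against level arms there too.

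Of 78 named log2 changes, TMM turned 3 in sign and ended 61 calls, and DESeq2 turned 33 and ended 34. snoRNA and snRNA scaling turned none and ended 47, and leaving out a library turned none and ended 111 of 312. Under DESeq2 the turned arms were for knockout against wild type miR-22-3p 0.86, miR-21a-5p 2.68, let-7c-5p 0.14, miR-31-5p 0.50, then for hsDicer against knockout miR-22-3p -1.21, miR-21a-5p -2.73, let-7c-5p -0.21, miR-125b-5p -0.77, let-7b-5p -0.059, miR-31-5p -0.068, miR-26a-5p -0.57, then for D1709A against hsDicer miR-21a-5p 0.65, miR-125b-5p 0.051, miR-31-5p 0.11, then for the double mutant against hsDicer miR-22-3p 2.41, miR-21a-5p 4.87, miR-29b-3p 1.48, let-7c-5p 0.067, miR-99b-5p 0.014, miR-125b-5p 3.43, let-7i-5p 1.23, let-7b-5p 3.96, miR-31-5p 2.95, then for K70A against knockout miR-22-3p -1.36, miR-21a-5p -2.95, let-7c-5p -0.14, miR-125b-5p -1.20, let-7b-5p -0.33, miR-31-5p -0.17, miR-26a-5p -0.75, then for Y971A/Y972A against knockout miR-22-3p -0.64, let-7c-5p -1.79, let-7b-5p -1.19. Under TMM they were miR-21a-5p 1.27 (the double mutant against hsDicer), let-7b-5p 0.32 (the double mutant against hsDicer), miR-21a-5p -0.62 (K70A against knockout).

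The replicate block, a term for replicate number (read length), gave 52 for knockout against wild type, 18 for D1320A against hsDicer, 10 for D1320A against knockout and 1 for the double mutant against knockout, and 3 changed ratios for D1320A against D1709A. For hsDicer against the knockout it gave 41, and no named arm changed sign or lost its call. It changed no other count by more than 1.5 times. The deviations of libraries with the same number from their group means correlated at 0.00427 to 0.463 (median 0.196) over 28 pairs of groups, 18 of them over 0.1, and because not every pair was, the numbers were not used as pairs. Every pair at 0.1 or less held D1320A or D1709A, and pairs of the other groups lay at 0.131 to 0.463. The main tests take no account of this structure. A library batch is not excluded by this: read length goes with the number in all 8 groups, and the miRNA share was higher in replicate 1 in each.

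With arms of 10 CPM or more, a choice that tests fewer arms, counts became 70 for knockout against wild type, 57 for hsDicer against knockout, 20 for D1320A against hsDicer, 30 for D1709A against hsDicer, 66 for the double mutant against hsDicer, 8 for D1320A against knockout, 9 for D1709A against knockout, 2 for the double mutant against knockout, 64 for K70A against knockout and 45 for Y971A/Y972A against knockout. With the replicate block added they were 76 for knockout against wild type, 75 for hsDicer against knockout, 27 for D1320A against hsDicer, 41 for D1709A against hsDicer, 76 for the double mutant against hsDicer, 30 for D1320A against knockout, 13 for D1709A against knockout, 3 for the double mutant against knockout, 81 for K70A against knockout and 61 for Y971A/Y972A against knockout. With limma on these arms they were 99 for knockout against wild type, 85 for hsDicer against knockout, 25 for D1320A against hsDicer, 48 for D1709A against hsDicer, 77 for the double mutant against hsDicer, 2 for Y971A/Y972A against hsDicer, 20 for D1320A against knockout, 14 for D1709A against knockout, 96 for K70A against knockout and 58 for Y971A/Y972A against knockout.

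With arms of 50 CPM or more, a choice that tests fewer arms, counts became 80 for knockout against wild type, 74 for hsDicer against knockout, 22 for D1320A against hsDicer, 42 for D1709A against hsDicer, 74 for the double mutant against hsDicer, 8 for D1320A against knockout, 15 for D1709A against knockout, 2 for the double mutant against knockout, 77 for K70A against knockout and 56 for Y971A/Y972A against knockout. With the replicate block added they were 84 for knockout against wild type, 77 for hsDicer against knockout, 29 for D1320A against hsDicer, 47 for D1709A against hsDicer, 78 for the double mutant against hsDicer, 31 for D1320A against knockout, 13 for D1709A against knockout, 2 for the double mutant against knockout, 84 for K70A against knockout and 66 for Y971A/Y972A against knockout. With limma on these arms they were 88 for knockout against wild type, 79 for hsDicer against knockout, 28 for D1320A against hsDicer, 46 for D1709A against hsDicer, 74 for the double mutant against hsDicer, 25 for D1320A against knockout, 14 for D1709A against knockout, 86 for K70A against knockout and 63 for Y971A/Y972A against knockout.

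With arms of 100 CPM or more, a choice that tests fewer arms, counts became 85 for knockout against wild type, 73 for hsDicer against knockout, 26 for D1320A against hsDicer, 43 for D1709A against hsDicer, 74 for the double mutant against hsDicer, 19 for D1320A against knockout, 15 for D1709A against knockout, 1 for the double mutant against knockout, 82 for K70A against knockout and 61 for Y971A/Y972A against knockout. With the replicate block added they were 85 for knockout against wild type, 75 for hsDicer against knockout, 29 for D1320A against hsDicer, 46 for D1709A against hsDicer, 75 for the double mutant against hsDicer, 31 for D1320A against knockout, 14 for D1709A against knockout, 82 for K70A against knockout and 61 for Y971A/Y972A against knockout. With limma on these arms they were 80 for knockout against wild type, 74 for hsDicer against knockout, 31 for D1320A against hsDicer, 47 for D1709A against hsDicer, 72 for the double mutant against hsDicer, 2 for Y971A/Y972A against hsDicer, 28 for D1320A against knockout, 16 for D1709A against knockout, 81 for K70A against knockout and 60 for Y971A/Y972A against knockout.

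For ratios, which edgeR called in no comparison without the replicate block, limma with a pseudocount of 0.5 called 10 for D1320A against hsDicer and 48 for D1320A against D1709A, and with 5 it called 11 for D1320A against hsDicer, 14 for D1709A against hsDicer, 3 for the double mutant against hsDicer and 51 for D1320A against D1709A. On hairpins with an arm of 10, 50 or 100 CPM limma called 2 for D1320A against hsDicer and 46 for D1320A against D1709A, then 2 for D1320A against hsDicer and 30 for D1320A against D1709A, then 6 for D1320A against hsDicer and 29 for D1320A against D1709A. Leaving out any library left all ratio counts of edgeR at 0.

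Leaving out each library in turn, where the lone library left in a group is assumed to vary like the others, gave counts of 8 to 31 for knockout against wild type, 5 to 35 for hsDicer against knockout, 3 to 11 for D1320A against hsDicer, 1 to 20 for D1709A against hsDicer, 10 to 54 for the double mutant against hsDicer, 0 to 3 for D1320A against knockout, 2 to 4 for D1709A against knockout, 0 to 1 for the double mutant against knockout, 6 to 28 for K70A against knockout, 2 to 31 for Y971A/Y972A against knockout, and 0 for the remaining comparisons of levels. Without knockout replicate 1, the library with most miRNA reads of the knockout pair, counts were 11 against wild type, 7 for hsDicer, 0 for D1320A, 2 for D1709A, 0 for the double mutant, 7 for K70A and 2 for Y971A/Y972A. Fewer libraries give less information, and the cause was not tested further.

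The median log2 ratio of 5p to 3p became 5.98 (wild type), 4.70 (knockout), 5.51 (hsDicer), 6.98 (D1320A), -4.42 (D1709A), 5.10 (the double mutant), 4.36 (K70A), 5.79 (Y971A/Y972A) over hairpins with 20 or more reads in the library, 0.82 (wild type), 0.37 (knockout), 0.97 (hsDicer), 6.14 (D1320A), -2.17 (D1709A), 0.76 (the double mutant), 1.85 (K70A), 0.33 (Y971A/Y972A) with 100 or more reads on each arm, and 0.62 (wild type), 0 (knockout), 0.76 (hsDicer), 3.74 (D1320A), -0.60 (D1709A), 0.013 (the double mutant), 0.34 (K70A), 0.11 (Y971A/Y972A) with a pseudocount of 5. The miRNA share of reads of 18 to 26 nt was 69.2% (wild type), 3.84% (knockout), 53.8% (hsDicer), 9.61% (D1320A), 12.96% (D1709A), 2.11% (the double mutant), 50.4% (K70A), 31.6% (Y971A/Y972A), a change that the smaller denominator makes. With 3 nt in place of 5 nt past the site, the 5p share was 0.325% (wild type), 66.7% (knockout), 5.32% (hsDicer), 16.2% (D1320A), 86.6% (D1709A), 63.8% (the double mutant), 1.77% (K70A), 6.27% (Y971A/Y972A), and the 3p share 0.00685% (wild type), 4.44% (knockout), 0.0450% (hsDicer), 96.0% (D1320A), 0.0855% (D1709A), 7.67% (the double mutant), 0.0471% (K70A), 0.0647% (Y971A/Y972A). In replicate 1 the 5p share went from 36.2% to 54.0% with the double mutant, 0.477% to 1.31% with hsDicer and 0.000892% to 0.0759% in wild type. Weighted by reads, mean lengths of 5p arms were 22.5 (wild type), 22.6 (hsDicer), 22.3 (D1320A), 22.5 (K70A), 22.5 (Y971A/Y972A) nt and of 3p arms 22.2 (wild type), 22.3 (hsDicer), 22.2 (D1709A), 22.2 (K70A), 22.1 (Y971A/Y972A) nt, the usual 3′ end of 5p arms was used by 77.2% (wild type), 78.4% (hsDicer), 76.6% (D1320A), 76.97% (K70A), 74.6% (Y971A/Y972A) and the usual 5′ end of 3p arms by 97.3% (wild type), 97.7% (hsDicer), 96.9% (D1709A), 96.7% (K70A), 93.5% (Y971A/Y972A) of reads. The cause was not tested.

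Libraries held 22166 to 123494 distinct sequences of 18 to 26 nt, with 41.01 to 286 reads for each. Replicates 1 and 2 held 38872 and 116448 in wild type, 40903 and 98846 with hsDicer, 45783 and 98552 with K70A and 48091 and 113015 with Y971A/Y972A. The knockout and the double mutant also held fewer in replicate 1, but D1320A (79843 and 74476) and D1709A (64400 and 50857) held more. In simulated data with the spread of the libraries, edgeR recovered 0 of 650 arms changed 64-fold, and with a low spread 604 of 650. At the spread of the libraries 386 to 446 simulated arms passed the filter, against 540 in the data. Changed arms were drawn whatever their level. In the data miR-21a-5p passed at -3.13 for D1320A against hsDicer, so the 0 is not the power for abundant arms. What depth alone does was not tested.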

Other observations

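The bounds of 100 reads, 90% and 10% were chosen after seeing the data. Over 90% of reads on 5p was seen in 56 of 95 and 61 of 161 hairpins in wild type, 52 of 89 and 68 of 153 with K70A, 43 of 72 and 47 of 133 with Y971A/Y972A and 11 of 110 and 9 of 85 with D1709A (replicates 1 and 2). Under 10% on 5p was seen in 27 and 33 hairpins in wild type, 21 and 32 with hsDicer, 1 and 2 with D1320A and 4 and 8 with the double mutant.

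Of long reads from the 5p start, the share that ended within 2 nt of the 3p start was 42.9% and 33.6% with D1709A, 25.3% and 4.28% with Y971A/Y972A, 11.8% and 9.37% in wild type (4 of 34 reads in replicate 1), 0.142% and 2.40% with K70A, 0.0253% and 0.913% with hsDicer, 0.126% and 0.587% with D1320A, 0.00641% and 0.476% with the double mutant and 0.00467% and 0.298% in the knockout.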
